A study of Homo sapiens with 8 samples.

How the data were processed

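The samples were 8 one-colour Agilent arrays, 2 for each of 4 groups of U937 or U937-B8 cells. The authors gave the growth medium as RPMI with serum, extraction with a Qiagen kit, and Cy3 labelling of 25 ng of total RNA with the Low Input Quick Amp kit. The file headers named array design 039494, genome build hg19 and Feature Extraction 11.0.1.1, while the authors' notes named Feature Extraction 9.1. The number of cells, the way resistance was raised, and whether the replicates were separate cultures were not given in the sources used here. The p-values therefore reflect the spread between these samples.

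The measured unit was the deposited processed signal, a scanner intensity with background removed, as named per the file headers. It was log2 transformed, and the 75th percentile of each array was subtracted. Control spots (1319) were left out of 61657 non-control and 1319 control spots, outlier spots were dropped, and spots of the same probe were averaged, which left 50683 probes. For 141 probes no spot remained on at least 1 array, and these were left out. A probe was kept where it lay well above background on both arrays of at least 1 group. No probe was saturated (0 on any array).

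Symbols came from the RefSeq accession of each probe, with its version removed, through a gene table of assembly GRCh38.p14. Of 50683 probes, 30878 carried a RefSeq-type accession, 28174 matched a symbol and 22509 had none. Because the design was made on hg19 and the table on a later assembly, the table was used for names and for which genes share a chromosome, and no position is given. The brightest probe stood for each gene, and 3568 genes had several probes that passed the filter. The test covered 13955 of 20503 genes with a symbol (68.1%), of which 12200 were well above background on all 8 arrays. Near-identical genes, such as the HLA class I and class II genes, the tryptases TPSAB1 and TPSD1, the defensins DEFA1 and DEFA3, and HSPA1A with HSPA1B, may cross-hybridise.

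Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, residual df 4, total df 7.09), and p-values were adjusted by Benjamini-Hochberg within each comparison. A gene counted as changed at an adjusted p under 0.05, with the count at 2-fold or more beside it. A value written as a ± b is a log2 difference with its standard error from that fit. Gene lists (26, with 534 of 610 entries tested) were written from general knowledge before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists of each comparison. Counts of list members use the adjustment over all genes, with counts adjusted over the list alone in square brackets. For genes above background in only 1 of the groups compared, signals of the dim group were raised to the lowest signal called well above background on the same array, and the difference is given as at least N-fold. Tables were read with jsonlite 2.0.0, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

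Each slide held 1 array of every group (slide 1: untreated replicate 1, 12 h replicate 2, washed-off replicate 2 and in-vorinostat replicate 1; slide 2: the others). The count with slide as a block and the medians within each slide stand beside the results. Among genes with a symbol, the named ones were chosen by rule. For each comparison these were the 6 largest rises and 6 largest falls of changed genes well above background on all 4 arrays, and the 3 rises and 3 falls with the largest bound among changed genes above background in 1 group only. For the interaction they were the 5 largest in each direction among changed genes above background on all 8 arrays. For lists they were up to 4 members with the smallest p. For the line difference shared without and with drug they were the 5 rises and 5 falls with the largest smaller difference. A fixed set was always looked at: CDKN1A, TXN, TXNIP, HDAC1, HDAC2, HDAC3, HDAC6, PSMB5, HSPA5, HSPA1A, SQSTM1, ABCB1, BCL2, BCL2L1, MCL1, MYC, TUBB3, CD14 and ITGAM. ABCB1, which encodes a drug efflux pump, did not pass the background filter. Some genes that these rules chose are left out of the text.

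Alternatives were normexp background correction (offset 50), quantile normalization, median scaling over bright probes, no filter on dim probes, only probes above background on all 8 arrays, the authors' value table, slide as a block, a replicate block, only the compared groups in the fit, trended and robust variance, the mean over probes, leaving out each array, an added 2-fold threshold, adjustment over all 6 contrasts, values within each slide, and camera with an estimated correlation. Added after the data were seen were keeping accessions without a symbol, and leaving out genes of chromosomes with a shifted median. Normexp used the raw median signal, because the deposited columns held no raw mean signal.

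The deposited value table holds 32896 probes on a log2 scale with column medians of 6.34 to 6.35. The authors do not state its normalization; its columns have nearly the same quantiles, as after quantile normalization. Its slope on the log2 raw median signal of the best-matching scanner file was 1.00 to 1.07, so scale and direction were settled. The authors' method of centring stays unstated. The untreated and in-vorinostat columns matched the scanner file of the other replicate of the same group better (r 0.999 to 1.00) than their own (0.991 to 0.996), and no group label was affected. The scanner files were used throughout.

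The fit was tested on simulated data, with the spread of these arrays and 50 shifted genes at each size. It called 8% of genes shifted by 0.5, 52% by 1, 92% by 2 and 100% by 3, with 0 in the wrong direction and 11 of 13723 unshifted genes called. Far more genes changed in the comparisons below, where these rates need not hold. A proteasome list shifted by 0.5 came back at 0.49, and a chromosome shifted by 0.5 at 0.50.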

Results

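U937 is a human line of monocytic cells from a histiocytic lymphoma, and vorinostat inhibits histone deacetylases, the enzymes that remove acetyl groups from histones and other proteins. U937-B8 is a derivative that grows in the drug. RNA was measured in untreated U937, in U937 after 12 h in 2 µM vorinostat, in U937-B8 kept 1 week without drug (washed off), and in U937-B8 kept in the drug, with 2 arrays per group. Across the 13955 genes tested, arrays of the same group correlated at 0.987 to 0.993 and arrays of different groups at 0.924 to 0.973. The first component held 50.4% of the variance and the second 29.3%. Replicates lay furthest apart in U937-B8 in vorinostat, where the SD over genes of their difference was 0.50, against 0.363 in untreated U937, 0.354 in U937 with drug and 0.365 in washed-off U937-B8. Each slide carried 1 array of every group.

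The first comparison asked which genes the drug changed in the parental line within 12 h. Among genes above background on all arrays compared, the largest rise was that of HLA-DMB, which loads peptides on MHC class II (5.65 ± 0.16, adjusted p = 4.69e-05). Next came the melanosome protein PMEL (5.20 ± 0.29), the tight-junction protein CGN (4.70), EGR2, a transcription factor of macrophage differentiation (4.40), the sterol carrier GRAMD1C (4.37) and the major vault protein MVP (4.30). MYC, the transcription factor that drives growth and ribosome production, was among the largest falls of such genes (−5.02 ± 0.22, adjusted p = 9.29e-05). The others were RGL4, a relative of Ral exchange factors (−5.46 ± 0.34), the cytokine IL17D (−4.50), the mitochondrial phospholipase PLD6 (−4.48), the acyl-CoA synthetase ACSL5 (−4.25) and SLAMF8, a receptor of macrophages (−4.10). Some genes were above background in 1 group only, so that the array bounds their change from below. CDKN1A, which encodes the cell-cycle inhibitor p21, was at least 24.2-fold higher, the adhesion protein JAML at least 24.9-fold and the tubulin-binding protein TPPP at least 23.5-fold. The cytokine-like CYTL1 was at least 16.4-fold lower, the scaffold WWC1 at least 11.9-fold and the activin subunit INHBB at least 11.3-fold. The signal of MYC, CDKN1A and 6 other genes on each array is drawn in the panel of genes by group.

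**Figure D1:**
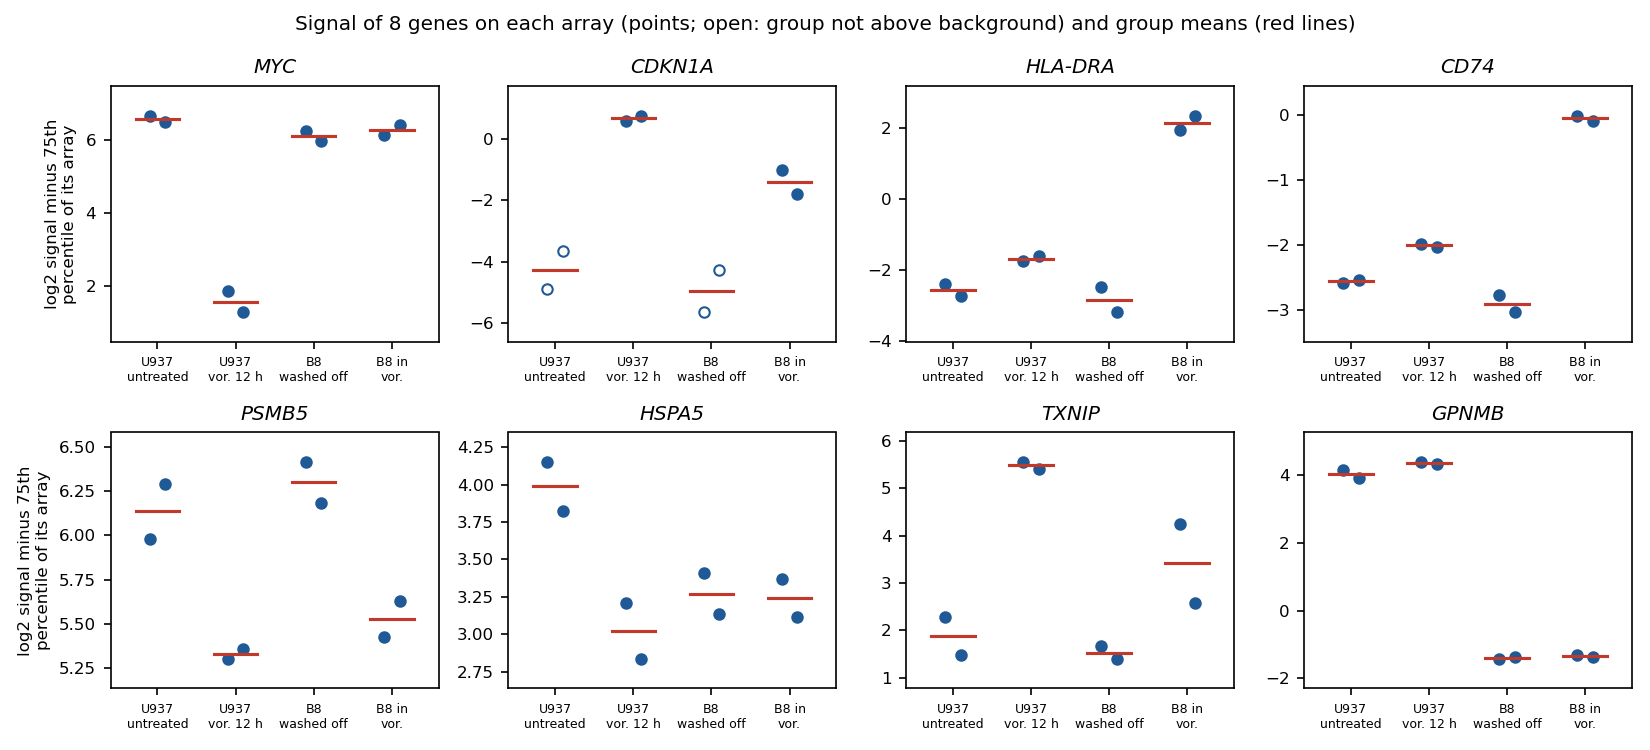
Signal of MYC, CDKN1A, HLA-DRA, CD74, PSMB5, HSPA5, TXNIP and GPNMB on each of the 8 arrays, on a log2 scale relative to the 75th percentile of the array. Red lines are group means, and open points mark groups in which no array was well above background.

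In limma, 6308 of 13955 genes (45.2%) changed, 3003 up and 3305 down, and 2975 of them by 2-fold or more (1429 up, 1546 down). With slide as a block 6115 genes changed, 5967 of them the same genes, and 81.8% of all genes tested had the same sign on both slides.

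RNAs of genes for ribosome production were lower in drug-treated U937. Of 27 measured genes of the MYC and ribosome biogenesis list, 0 rose and 26 fell [0 and 26], with a median of −1.34 (−1.16 and −1.55 on the 2 slides, camera adjusted p = 2.73e-11, slide block 4.31e-11, adjusted p = 0.863 with an estimated correlation). Besides MYC, these included the small-subunit factor UTP20 (−3.26), the ribosome assembly factor RRS1 (−2.43) and the nucleolar protein MYBBP1A (−2.41). Cell-cycle inhibitors and growth-arrest genes went up, 9 up and 1 down of 15 [9 and 1], median 0.96 (slides 1.04 and 0.83, adjusted p = 0.0107, slide block 0.0105, adjusted p = 0.863 with an estimated correlation). Examples were the antiproliferative genes BTG2 (1.79) and BTG1 (1.57) and the CDK4 inhibitor CDKN2D (1.26). Thioredoxin and oxidative-stress genes also rose, 13 up and 1 down of 24 [13 and 1], median 0.68 (slides 0.79 and 0.48, adjusted p = 0.0107, slide block 0.0114, adjusted p = 0.863 with an estimated correlation). TXNIP, which binds and inhibits thioredoxin, rose by 3.61 ± 0.51 and the ferritin heavy chain FTH1 by 2.76, while thioredoxin itself, TXN, had −0.32 (adjusted p = 0.0899). Cytosolic chaperones and heat-shock genes fell, 3 up and 15 down of 29 [3 and 16], median −0.68 (slides −0.39 and −0.83, adjusted p = 0.0376, slide block 0.0393, adjusted p = 0.912 with an estimated correlation). FKBP4, a cochaperone of HSP90, had −2.09 ± 0.21 and the HSP70 exchange factor HSPH1 −1.72, against 1.54 for the cochaperone BAG3 and 1.18 for the inducible HSP70 gene HSPA1A. Without untreated replicate 2 this list had an adjusted p of 0.0698, without 12 h replicate 1 of 0.124, and without the genes of the 3 chromosomes described with the line difference of 0.0635 (median −0.75). The last setting also ended the thioredoxin call (median 0.59, adjusted p = 0.0581), so the shifts of these lists stayed about as large with fewer genes. The median of the cell-cycle inhibitors was 0.43 with normexp and 0.60 in the authors' value table.

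Other protein-handling lists did not pass in treated U937. The proteasome list had 0 up and 7 down of 32 [0 and 4], median −0.10 (adjusted p = 0.361), with −0.81 ± 0.17 for PSMB5, the catalytic subunit bound by bortezomib, and −0.71 for the lid subunit PSMD7. Genes of the immunoproteasome and MHC class I split 5 up and 5 down of 17 [6 and 6], with a median of 0.06 but a mean of −0.26 and a test directed down (adjusted p = 0.842). Its catalytic subunits PSMB10 (−2.91) and PSMB8 (−1.81) and the peptide transporter TAP2 (−1.37) fell. ER chaperones and genes of the unfolded protein response had 1 up and 9 down of 32 [0 and 9], median −0.24 (adjusted p = 0.175), with falls of the ER chaperone HSPA5 (−0.97) and the stress factors XBP1 (−1.78), TRIB3 (−1.61) and ATF4 (−1.27). ER translocation, export and degradation had 9 up and 3 down of 41 [8 and 1], median 0.04 (adjusted p = 0.697). Ubiquitin, autophagy and lysosome genes had 9 up and 2 down of 29 [9 and 2], median 0.19 (adjusted p = 0.0911, and 0.0254 to 0.0434 in 4 settings that passed), with rises of the autophagy genes WIPI1 (2.55), GABARAPL1 (2.44) and SQSTM1 (1.57).

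Lists of cell death, differentiation and immune function did not pass in treated U937 with the settings used throughout, but 2 of them did in others. Pro-apoptotic genes had 8 up and 3 down of 20 [8 and 3], median 0.29 (adjusted p = 0.0871, and 0.0275 to 0.0488 in 3 settings that passed), led by the BH3-only genes BMF (4.09) and HRK (−2.85) and the apoptosome gene APAF1 (2.08). Anti-apoptotic genes had 3 up and 2 down of 11 [3 and 3], median 0.01 (adjusted p = 0.844), with 0.64 for MCL1. Monocyte and macrophage genes had 10 up and 5 down of 25 [10 and 5], median 0.21 (adjusted p = 0.330), including the integrin ITGAM (1.27), the endotoxin receptor CD14 (0.91) and the myeloid transcription factor SPI1 (−1.89). Granule and progenitor genes had 2 up and 10 down of 17 [3 and 10], median −0.67 (adjusted p = 0.153), with −2.47 for proteinase 3, PRTN3, and −1.79 for MYB. MHC class II genes had 6 up and 1 down of 10 [6 and 1], median 0.89 (adjusted p = 0.0786, and 0.0310 to 0.0486 in 7 settings that passed), interferon-stimulated genes 11 up and 8 down of 25 [12 and 8], median 0.31 (adjusted p = 0.410), and cell-cycle genes 8 up and 8 down of 40 [8 and 8], median 0.06 (adjusted p = 0.697). Inflammatory genes had 6 up and 6 down of 19 [6 and 6], with a median of −0.26 but a mean of 0.49 and a test directed up (adjusted p = 0.842); the chemokine CCL3 rose by 2.38 and the transcription factor NFKB1 fell by 1.6.

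Of the remaining lists in treated U937, deacetylases and acetyltransferases had 7 up and 6 down of 22 [7 and 9], median 0.09 (adjusted p = 0.807), with 1.04 for HDAC3, 0.68 for HDAC1 and 0.52 for HDAC6, whose other probe had the opposite sign. Histone genes had 4 up and 1 down of 16 [4 and 1], with a median of −0.16 but a mean of 0.19 and a test directed up (adjusted p = 0.690). Glycolysis and hypoxia genes had 8 up and 7 down of 24 [10 and 7], median −0.19, mean 0.24 and a test directed up (adjusted p = 0.820), and cholesterol synthesis 6 up and 2 down of 20 [6 and 2], median 0.30 (adjusted p = 0.410). Of 11 drug efflux genes 5 were measured, 1 up and 3 down, with a median of −0.76 but a mean of 0.06 (adjusted p = 0.511). Markers of other cell types were measured in part. Neuronal markers (9 of 18) had 6 up and 1 down, median 1.1 (adjusted p = 0.0786, and 0.0413 to 0.0474 in 2 settings that passed), among them tubulin TUBB3 (1.79). Epithelial and fibroblast markers (7 of 17) had 2 up and 0 down, median −0.09 with a mean of 0.85 (adjusted p = 0.511). T and B cell markers (8 of 16) had 2 up and 1 down, median 0.12 (adjusted p = 0.793), and erythroid and megakaryocyte markers (10 of 17) 0 up and 2 down, median −0.13 (adjusted p = 0.538).

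The second comparison asked how U937-B8 differed from U937 when neither had drug in the medium. Among genes above background on all 4 arrays and with close replicates, the germ-line protein TEX19 rose most (5.74 ± 0.20, adjusted p = 2.99e-05), with the lectin ITLN1 (5.45), the sorting nexin SNX19 (4.13), the secreted protein ZG16B (4.07) and CCDC116, a coiled-coil protein (3.74). The neutrophil defensin DEFA3 rose by 9.78 ± 0.73, with SDs between replicates of 1.27 in U937 and 1.40 in U937-B8. Of genes above background on all 4 arrays, the ceramide synthase CERS1 fell most (−6.78 ± 0.19, adjusted p = 9.38e-06), then GPNMB, a glycoprotein of macrophages and melanocytes (−5.41 ± 0.13), the dynein assembly factor DNAAF3 (−4.99), EMC10, a subunit of the ER membrane complex (−4.98), and the mast-cell tryptases TPSD1 (−4.82) and TPSAB1 (−4.73). The kallikrein KLK1 was at least 54.3-fold higher, the extracellular superoxide dismutase SOD3 at least 20.7-fold and the apolipoprotein APOC1 at least 14.3-fold. The claudin CLDN5 was at least 47.6-fold lower, the Notch ligand DLL3 at least 37.6-fold and the glutamate receptor subunit GRIN2D at least 32.5-fold. MYC (−0.47, adjusted p = 0.221) and PSMB5 (0.16, adjusted p = 0.576) did not pass. BCL2, which blocks apoptosis, had −0.77 (adjusted p = 0.0351).

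In limma, 1914 genes (13.7%) differed, 874 higher and 1040 lower, and 876 by 2-fold or more (384 higher, 492 lower). With slide as a block 1631 differed, 1561 of them the same genes, and 74.1% of all genes tested had the same sign on both slides. The count fell to 730 without untreated replicate 1, to 797 without untreated replicate 2, to 702 without washed-off replicate 1 and to 766 without washed-off replicate 2.

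Genes that share a chromosome moved together between the lines. The 831 tested genes on the chromosome that carries CTSD had a median of 0.50 (0.50 and 0.49 on the 2 slides) and supplied 274 of the 874 genes higher in washed-off U937-B8 (31.4%, against 5.95% of genes tested). The 1052 genes on the chromosome that carries EMC10, CERS1, DNAAF3, DLL3 and GRIN2D had a median of −0.36 and supplied 261 of the 1040 lower genes (25.1%, against 7.54%). The 573 genes on the chromosome that carries CD74 had a median of 0.22. The other autosomes had medians of −0.15 to 0.02. Without the genes of those 3 chromosomes, 1058 of 11499 genes differed, 428 higher and 630 lower.

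Because the series title names a signature of protein processing, the 6 protein-handling lists were compared between the lines in full. Immunoproteasome and MHC class I genes were the only such list to pass without drug, 7 higher and 0 lower of 17 [7 and 0], median 0.33 (slides 0.73 and 0.27, adjusted p = 6.57e-05, slide block 9.18e-05, adjusted p = 0.986 with an estimated correlation). The median was 0.23 without untreated replicate 1 and 0.54 without untreated replicate 2. The class I heavy chains HLA-F (1.32), HLA-B (1.01 ± 0.14) and HLA-C (0.93) rose. The proteasome list had 2 higher and 2 lower of 32 [2 and 2], median 0.10 (slides 0.14 and 0.03, adjusted p = 0.476). PSMD13 (0.70) and PSMA1 (0.56), which rose, lie on the chromosome of CTSD, while PSMA6 had −0.78 and PSMD8, on the chromosome of EMC10, −0.62. ER chaperones had 2 higher and 3 lower of 32 [2 and 5], with a median of 0.06 and a mean of −0.06 (slides 0.05 and 0.04, adjusted p = 0.967). The ER chaperone HYOU1, on the chromosome of CTSD, had 1.11 ± 0.17, the glutathione-degrading stress gene CHAC1 −1.62, and PPP1R15A, which restarts translation after stress and lies on the chromosome of EMC10, −1.59. HSPA5 had −0.72 (adjusted p = 0.0590). ER translocation, export and degradation had 1 higher and 0 lower of 41 [1 and 0], median 0.14 (slides 0.15 and 0.13, adjusted p = 0.135). That gene was the ubiquitin ligase SYVN1 (0.88), also on the chromosome of CTSD. Cytosolic chaperones had 1 higher and 1 lower of 29 [1 and 1], median −0.10 (slides −0.05 and −0.20, adjusted p = 0.705), the cochaperone STIP1 (0.69, chromosome of CTSD) and the heat-shock gene HSPA6 (−0.89). Ubiquitin, autophagy and lysosome genes had 3 higher and 0 lower of 29 [3 and 0], median 0.08 (slides 0.18 and 0.01, adjusted p = 0.135), among them the lysosomal protease CTSD itself (1.71 ± 0.17) and the lysosomal membrane protein LAMP2 (0.64). In the authors' value table the proteasome (adjusted p = 0.0493), ER translocation (adjusted p = 0.0471) and ubiquitin lists (adjusted p = 0.0493) passed upward, and ER translocation also after quantile normalization (adjusted p = 0.0441), while without the 3 chromosomes the latter pair had medians of 0.11 and 0.06 (adjusted p = 0.364). The members of these lists are drawn in the panel of protein-handling genes.

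**Figure D2:**
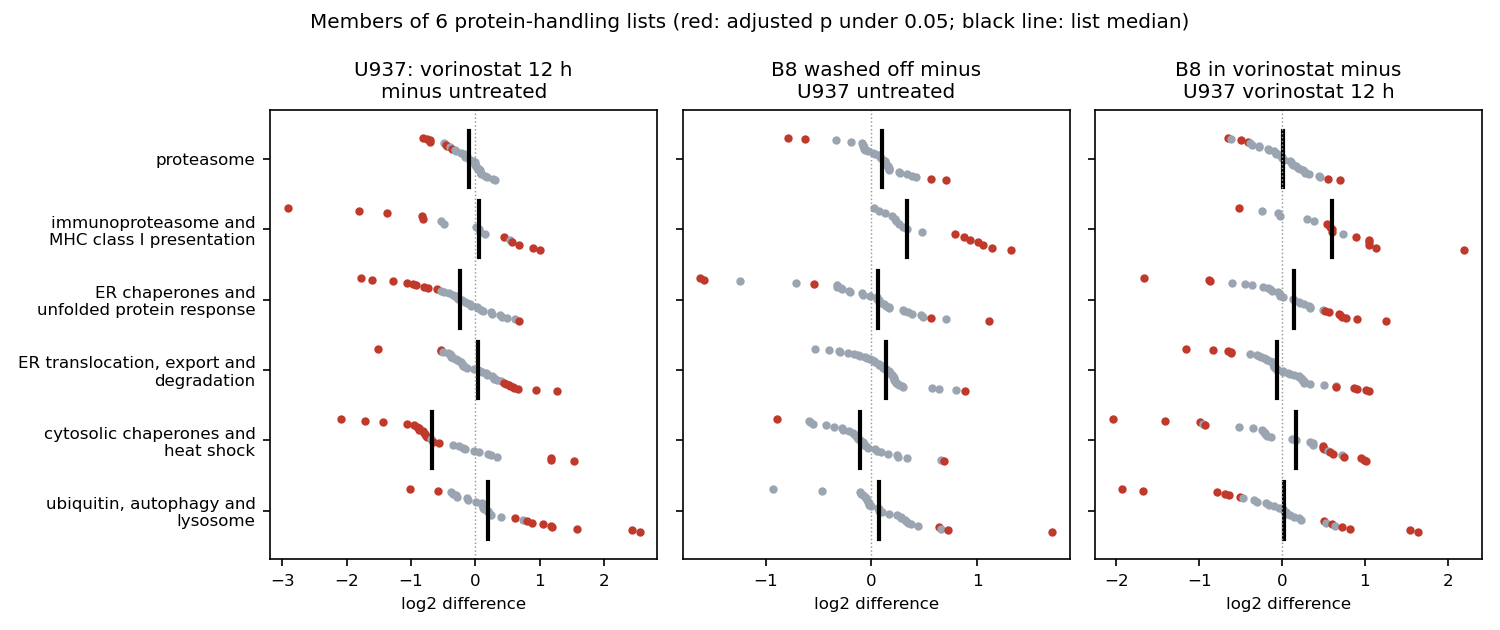
Log2 differences of the measured members of 6 protein-handling lists after 12 h of vorinostat in U937 (left), between washed-off U937-B8 and untreated U937 (middle), and between U937-B8 in vorinostat and U937 after 12 h in the drug (right). Red points have an adjusted p under 0.05, and black lines are list medians.

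Inflammatory genes were lower in washed-off U937-B8, 0 higher and 5 lower of 19 [0 and 5], median −0.45 (slides −0.59 and −0.22, adjusted p = 0.0187, slide block 0.0117, adjusted p = 0.986 with an estimated correlation). The median was −0.22 with normexp, −0.25 with no filter on dim probes, −0.26 in the authors' value table and −0.30 without washed-off replicate 2. The chemokines CCL2 (−3.98) and CCL3 (−3.45 ± 0.29) and the cytokine IL1B (−2.18) were among them. No other list passed without drug with the settings used throughout. Histone genes had 0 higher and 1 lower of 16 [1 and 3], median −0.48 (adjusted p = 0.0513, slide block 0.0117, and under 0.05 in 10 further settings), and cell-cycle genes 0 higher and 5 lower of 40 [1 and 7], median −0.18 (adjusted p = 0.0787, and 0.00909 to 0.0278 in 3 settings that passed). Cholesterol synthesis had 2 higher and 0 lower of 20 [2 and 0], median 0.20 (adjusted p = 0.0888, and 0.0387 to 0.0493 in 4 settings that passed). Monocyte and macrophage genes had 1 higher and 5 lower of 25 [3 and 6], median −0.04 (adjusted p = 0.538), with the scavenger receptor CD36 at least 14.0-fold lower and the protease MMP9 at −3.14. Pro-apoptotic genes had 1 higher and 5 lower of 20 [2 and 5], median −0.10 (adjusted p = 0.538), and HRK was at least 18.8-fold lower. Anti-apoptotic genes had 3 higher and 1 lower of 11 [3 and 1], median 0.22 (adjusted p = 0.410), among them the apoptosis inhibitors BIRC3 (1.05) and BIRC2 (0.91), which lie on the chromosome of CTSD. MHC class II genes had 1 higher and 0 lower of 10 [2 and 0], median 0.09 (adjusted p = 0.584). Of the other cell types, T and B cell markers had 1 higher and 0 lower of 8 [1 and 0] (median −0.21, adjusted p = 0.967), erythroid markers 1 and 2 of 10 (0.01, adjusted p = 0.967), epithelial markers 0 and 0 of 7 (0.04, adjusted p = 0.956) and neuronal markers 1 and 2 of 9 (median 0.27, mean −0.15, adjusted p = 0.967).

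The third comparison set U937-B8 in vorinostat against U937 after 12 h in it, so that line and length of exposure cannot be told apart. Among genes above background on all 4 arrays, SOD3 had the largest rise (7.04 ± 0.40, adjusted p = 0.000129), then TEX19 (5.81), the phosphatase regulator PPP1R27 (5.20), the actin-bundling protein FSCN1 (5.0), MYC (4.72 ± 0.22) and the galactose mutarotase GALM (4.70). GPNMB had the largest fall of such genes (−5.69 ± 0.13, adjusted p = 1.20e-05), followed by the histone gene H3C11 (−4.88), CD36 (−4.79), the vesicle GTPase RAB27B (−4.76), the fractalkine receptor CX3CR1 (−4.20) and CCL3 (−4.18). KLK1 was at least 49.5-fold higher, the prostaglandin receptor PTGDR2 at least 43.5-fold and the adhesion protein CADM1 at least 41.7-fold. TPSAB1 was at least 119-fold lower, TPSD1 at least 92.4-fold and the membrane protein EMP1 at least 75.9-fold.

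In limma, 5529 genes (39.6%) differed, 2672 higher and 2857 lower, and 2222 by 2-fold or more (1006 higher, 1216 lower). With slide as a block 5250 differed, 5077 of them the same genes, 77.2% of all genes tested had the same sign on both slides, and the count was 3066 without 12 h replicate 2.

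MYC and ribosome biogenesis genes were higher in U937-B8 in vorinostat, 21 higher and 0 lower of 27 [22 and 0], median 0.80 (slides 0.71 and 0.97, adjusted p = 3.90e-08, slide block 4.70e-08, adjusted p = 0.666 with an estimated correlation). Besides MYC, the ribosome assembly gene NOP16 rose by 2.09 and MYBBP1A by 1.69. Cell-cycle inhibitors were lower, 1 higher and 8 lower of 15 [1 and 9], median −0.95 (slides −0.91 and −0.66, adjusted p = 0.0222, slide block 0.0240, adjusted p = 0.666 with an estimated correlation), with CDKN1A at −2.08 ± 0.54, CDKN2D at −1.55 and the antiproliferative gene TOB1 at −1.25. Cell-cycle genes were lower too, 2 higher and 20 lower of 40 [2 and 22], median −0.50 (slides −0.61 and −0.36, adjusted p = 0.000419, slide block 0.000465, adjusted p = 0.666 with an estimated correlation), among them the ribonucleotide reductase subunit RRM2 (−2.06) and the mitotic kinesin KIF11 (−1.29). Pro-apoptotic genes were lower, 3 higher and 12 lower of 20 [3 and 12], median −0.79 (slides −0.70 and −0.53, adjusted p = 0.0222, slide block 0.0240, adjusted p = 0.797 with an estimated correlation), including the BH3-only genes BMF (−2.56) and PMAIP1 (−1.68). Monocyte and macrophage genes were lower, 4 higher and 9 lower of 25 [4 and 12], median −0.54 (slides −0.35 and −0.89, adjusted p = 0.0436, slide block 0.0408, adjusted p = 0.764 with an estimated correlation). MMP9 had −3.19, the integrin ITGAX was at least 27.0-fold lower, and SPI1 rose by 1.76. MHC class II genes were higher, 5 higher and 0 lower of 10 [6 and 0], median 1.27 (slides 1.29 and 1.26, adjusted p = 0.0262, slide block 0.0240, adjusted p = 0.666 with an estimated correlation), led by the chains HLA-DRA (3.84) and HLA-DRB1 (2.29) and the invariant chain CD74 (1.96). The monocyte list lost its call in 5 settings, with adjusted p from 0.0524 with the mean over probes to 0.406 over probes above background on all 8 arrays, and without 12 h replicate 1, in-vorinostat replicate 2 or the 3 chromosomes (median −0.58). The class II list lost it without 12 h replicate 1 (adjusted p = 0.0877) and without the 3 chromosomes (median 0.83, adjusted p = 0.0544). With normexp the medians of the cell-cycle inhibitor, monocyte and class II lists were −0.48, −0.32 and 0.70, and the inhibitors had −0.59 over probes above background on all 8 arrays. Thioredoxin and oxidative-stress genes had 3 higher and 11 lower of 24 [3 and 13], median −0.60 (adjusted p = 0.0913, and 0.0103 to 0.0486 in 5 settings that passed). Inflammatory genes had 1 higher and 6 lower of 19 [1 and 7], median −0.55 (slides 0.06 and −1.44, adjusted p = 0.0872, and 0.00215 to 0.0460 in 5 settings that passed).

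Of the protein-handling lists with drug in both media, immunoproteasome and MHC class I genes again passed, 10 higher and 1 lower of 17 [11 and 1], median 0.60 (slides 0.72 and 0.53, adjusted p = 0.00855, slide block 0.0110, adjusted p = 0.666 with an estimated correlation), with PSMB10 (2.20 ± 0.20), PSMB8 (1.06) and HLA-C (1.05) higher. Proteasome genes had 2 higher and 3 lower of 32 [1 and 1], median 0.01 (slides −0.12 and 0.21, adjusted p = 0.901). ER chaperones had 8 higher and 3 lower of 32 [8 and 3], median 0.14 (slides 0.04 and 0.22, adjusted p = 0.363), with the chaperone CANX (1.26), ATF4 (0.91) and XBP1 (0.77) higher and PPP1R15A (−1.66) lower. ER translocation, export and degradation had 5 higher and 5 lower of 41 [3 and 3], with a median of −0.06, a mean of 0.04 and slide medians of −0.19 and 0.19 (adjusted p = 0.934). Cytosolic chaperones had 9 higher and 4 lower of 29 [10 and 4], median 0.17 (slides −0.03 and 0.54, adjusted p = 0.537), FKBP4 at 0.99 and BAG3 at −2.05. Ubiquitin, autophagy and lysosome genes had 6 higher and 6 lower of 29 [6 and 6], median 0.03 (adjusted p = 0.901), with CTSD at 1.64 and the autophagy receptor SQSTM1 at −1.68.

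Much of the difference between the lines held without and with drug. Both comparisons found 555 genes higher (167 by chance) and 636 lower (213 by chance), against 40 and 34 in opposite directions (179 and 199 by chance), and r across genes, which are not independent replicates, was 0.541. Higher in both were TEX19 (5.74 and 5.81), ZG16B (4.07 and 4.54), SNX19 (4.13 and 3.92), FSCN1 (3.64 and 5.0) and the lymphocyte and monocyte surface protein CD52 (3.47 and 3.76). Lower in both were GPNMB (−5.41 and −5.69), EMC10 (−4.98 and −3.94), H3C11 (−3.64 and −4.88), the membrane protein PALM (−3.47 and −3.53) and CCL3 (−3.45 and −4.18). The chromosome of CTSD had medians of 0.50 without and 0.49 with drug and that of CD74 0.22 and 0.32, but that of EMC10 had −0.36 and −0.17, the latter within the −0.25 to 0.15 of the other autosomes with drug. The 1191 shared genes numbered 1016 with slide as a block, 507 without untreated replicate 1, 564 without untreated replicate 2, 498 without washed-off replicate 1, 538 without washed-off replicate 2 and 680 without the 3 chromosomes.

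The fourth comparison asked what vorinostat in the medium changed in U937-B8. Of genes above background on all 4 arrays, CREB3L3, a transcription factor of the ER membrane, had the largest rise (5.54 ± 0.37, adjusted p = 0.000350), followed by HLA-DRA (5.0 ± 0.27), CGN (3.97), the LIM-only protein LMO1 (3.92 ± 0.49), HLA-DMB (3.89 ± 0.16) and the cannabinoid receptor CNR2 (3.82 ± 0.96). RGL4 had the largest fall of such genes (−5.00 ± 0.34), then the chemokine receptor CXCR3 (−4.03), MS4A3, a membrane protein of myeloid progenitors (−3.59), PRTN3 (−3.31), the testis actin relative ACTL8 (−3.29) and the acylphosphatase ACYP2 (−3.24). CADM1 was at least 36.0-fold higher, PTGDR2 at least 34.3-fold and the zinc-finger protein ZC4H2 at least 10.8-fold. DEFA3 was at least 1313-fold lower, although its washed-off replicates lay far apart, as given with the second comparison. The chemokine CCL23 was at least 12.8-fold lower and the neutrophil granule protein BPI at least 7.36-fold. CDKN1A was at least 5.46-fold higher, while MYC had 0.17 (adjusted p = 0.608). TXNIP rose by 1.88, but its log2 signals in U937-B8 in vorinostat lay apart (4.26 in replicate 1 and 2.57 in replicate 2).

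In limma, 3648 genes (26.1%) changed, 1659 up and 1989 down, and 1428 by 2-fold or more (754 up, 674 down). With slide as a block 3364 changed, 3211 of them the same genes, 75.5% of all genes tested had the same sign on both slides, and the count fell to 1362 without washed-off replicate 1 and to 1909 without washed-off replicate 2.

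MHC class II genes rose furthest of all lists in U937-B8 with drug, 6 up and 1 down of 10 [7 and 1], median 2.72 (slides 2.67 and 2.77, adjusted p = 0.000143, slide block 0.000170, adjusted p = 0.509 with an estimated correlation). With HLA-DRA and HLA-DMB rose HLA-DMA, its partner (3.05), and CD74 (2.86 ± 0.14). MYC and ribosome biogenesis genes fell less than in U937, 0 up and 8 down of 27 [0 and 12], median −0.44 (slides −0.42 and −0.40, adjusted p = 0.000362, slide block 0.000269, adjusted p = 0.764 with an estimated correlation), with UTP20 at −1.50. Granule and progenitor genes fell, 1 up and 8 down of 17 [2 and 10], median −0.54 (slides −0.61 and −0.47, adjusted p = 0.0310, slide block 0.0282, adjusted p = 0.764 with an estimated correlation), among them PRTN3 and the neutrophil elastase ELANE (−2.24). Cytosolic chaperones fell, 0 up and 6 down of 29 [0 and 6], median −0.34 (slides −0.47 and −0.24, adjusted p = 0.0352, slide block 0.0308, adjusted p = 0.866 with an estimated correlation), with the chaperonin subunits CCT5 (−1.0) and CCT2 (−0.85). Cell-cycle genes fell, 0 up and 9 down of 40 [0 and 9], median −0.26 (slides −0.29 and −0.33, adjusted p = 0.0414, slide block 0.0419, adjusted p = 0.764 with an estimated correlation), with the mitotic kinase PLK1 at −0.92. Without in-vorinostat replicate 1 the granule, chaperone and cell-cycle lists lost their calls, as did the latter pair without washed-off replicate 1 and all of them without the 3 chromosomes (adjusted p from 0.0742 to 0.167), where their medians stayed at −0.54, −0.35 and −0.22. Without in-vorinostat replicate 1 the medians of the chaperone and ribosome lists were −0.19 and −0.27, and without in-vorinostat replicate 2 that of the chaperones was −0.54. With normexp the class II median was 1.64 and the granule median −0.25. The cell-cycle call was also lost with quantile normalization (adjusted p = 0.0920) and in the authors' value table (adjusted p = 0.0547). The proteasome list had 0 up and 1 down of 32 [0 and 0], median −0.18 (adjusted p = 0.0544), and the member that fell was PSMB5 (−0.77, adjusted p = 0.0156). It passed downward in 8 other settings, with adjusted p from 0.00276 with no filter on dim probes to 0.0442 with the mean over probes. Immunoproteasome and MHC class I genes had 1 up and 6 down of 17 [1 and 6], with a median of 0.02 but a mean of −0.20 and a test directed down (adjusted p = 0.455). Thioredoxin and oxidative-stress genes had 5 up and 2 down of 24 [7 and 2], median 0.26 (adjusted p = 0.0572, and 0.0253 to 0.0473 in 3 settings that passed).

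Both lines shared part of the drug response. In both, 1111 genes rose (357 by chance) and 1337 fell (471 by chance), against 73 and 48 in opposite directions (428 and 393 by chance). Across genes r was 0.604, and the slope of the U937-B8 response on that of U937 was 0.463. The shared rises included HLA-DMB (5.65 and 3.89), CGN (4.70 and 3.97), MVP (4.30 and 2.89) and BMF (4.09 and 2.92), and the shared falls RGL4 (−5.46 and −5.00). The 2448 shared genes numbered 2262 with slide as a block, 1039 without washed-off replicate 1 and 1413 without washed-off replicate 2. Both pairs of comparisons are drawn in the scatter of drug and line differences.

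**Figure D3:**
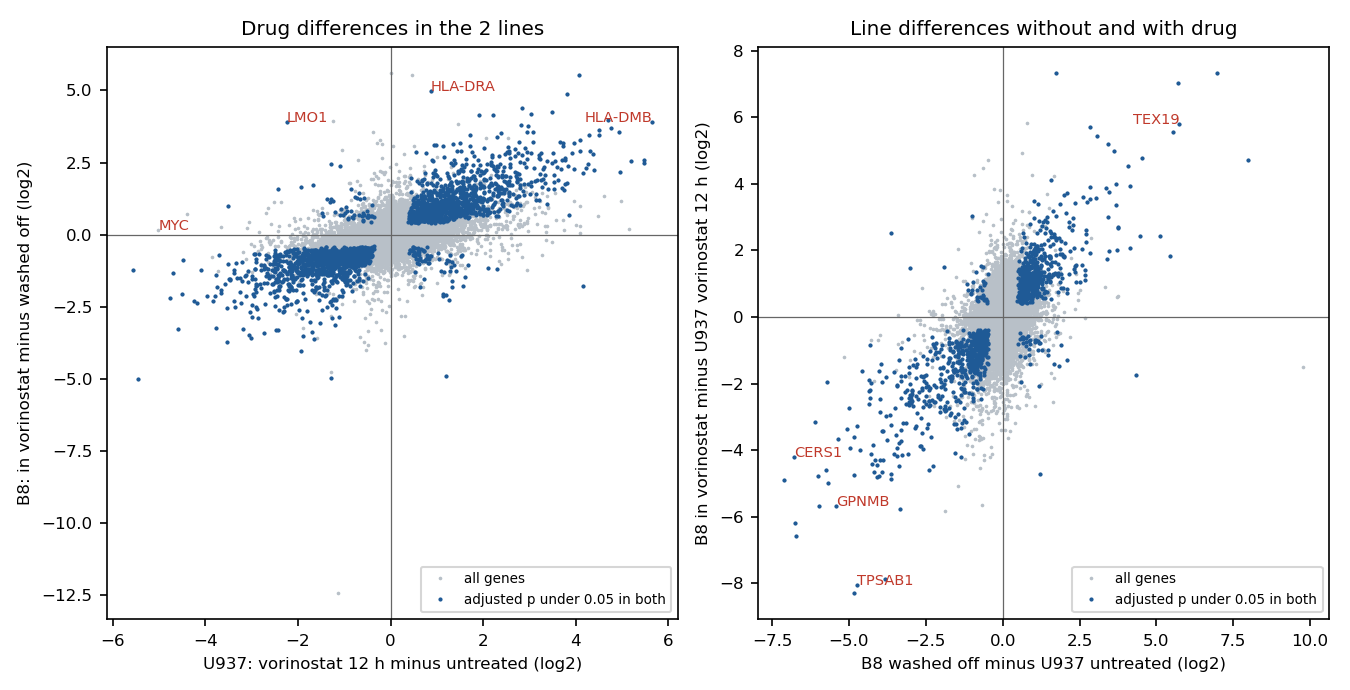
Left, log2 differences with drug in U937 after 12 h against those in U937-B8. Right, log2 differences between the lines without drug against those with drug. Blue points have an adjusted p under 0.05 in both comparisons on their axes, and some of them are named.

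The fifth comparison set U937-B8 in vorinostat against untreated U937, the state of the resistant line in its usual medium. Among genes above background on all 4 arrays, TEX19 had the largest rise (6.88 ± 0.20, adjusted p = 9.69e-06), then CREB3L3 (6.78), CD52 (6.44), HLA-DMB (5.50), HLA-DRA (4.72) and ITLN1 (4.66). GPNMB had the largest fall of such genes (−5.36 ± 0.13), then EPS8L1, a regulator of actin (−5.17), the epithelial defensin DEFB1 (−5.05), the methyltransferase relative PRDM8 (−4.38, its other probe in the opposite direction) and DNAAF3 (−4.30). SOD3 was at least 172-fold higher and KLK1 at least 40.8-fold. TPSAB1 was at least 167-fold lower, TPSD1 at least 133-fold and CLDN5 at least 42.5-fold. In limma, 4837 genes (34.7%) differed, 2051 higher and 2786 lower, and 2004 by 2-fold or more (915 higher, 1089 lower). With slide as a block 4521 differed, 4362 of them the same genes, 81.2% of all genes tested had the same sign on both slides, and the count was 2874 without untreated replicate 1 and 2897 without untreated replicate 2.

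Against untreated U937, MHC class II genes were higher in U937-B8 in vorinostat, 7 higher and 1 lower of 10 [7 and 1], median 2.86 (slides 2.76 and 2.95, adjusted p = 0.000171, slide block 0.000200, adjusted p = 0.583 with an estimated correlation). Ubiquitin, autophagy and lysosome genes were higher, 11 higher and 1 lower of 29 [12 and 1], median 0.36 (slides 0.43 and 0.40, adjusted p = 0.0118, slide block 0.0158, adjusted p = 0.873 with an estimated correlation), among them WIPI1 (1.86) and CTSD (1.27). Cholesterol synthesis was higher, 4 higher and 0 lower of 20 [4 and 0], median 0.32 (slides 0.21 and 0.43, adjusted p = 0.0259, slide block 0.0306, adjusted p = 0.921 with an estimated correlation), with the sterol carrier STARD4 at 1.59 and the reductase DHCR7 at 1.00. MYC and ribosome biogenesis genes were lower, 0 higher and 16 lower of 27 [0 and 20], median −0.63 (slides −0.69 and −0.47, adjusted p = 0.000163, slide block 0.000110, adjusted p = 0.921 with an estimated correlation), although MYC itself had −0.30 (adjusted p = 0.328). Cell-cycle genes were lower, 1 higher and 19 lower of 40 [1 and 20], median −0.53 (slides −0.56 and −0.38, adjusted p = 0.000613, slide block 0.000775, adjusted p = 0.873 with an estimated correlation), such as the chromatin reader UHRF1 (−1.15) and the checkpoint kinase BUB1B (−1.03). Cytosolic chaperones were lower, 1 higher and 10 lower of 29 [1 and 12], median −0.50 (slides −0.58 and −0.41, adjusted p = 0.0326, slide block 0.0315, adjusted p = 0.921 with an estimated correlation). Granule genes were lower too, 2 higher and 8 lower of 17 [2 and 8], median −0.44 (slides −0.71 and −0.28, adjusted p = 0.0326, slide block 0.0315, adjusted p = 0.873 with an estimated correlation). Without in-vorinostat replicate 1 the chaperone and granule lists lost their calls, the chaperones also without untreated replicate 2, and cholesterol synthesis without in-vorinostat replicate 2 (adjusted p = 0.188). Without the 3 chromosomes the granule (median −0.36, adjusted p = 0.291) and cholesterol (median 0.22, adjusted p = 0.0609) calls were lost, and the granule call also with quantile normalization (adjusted p = 0.0646) and in the authors' value table (adjusted p = 0.0628). Without in-vorinostat replicate 1 the medians of the chaperone and granule lists were −0.30 and −0.19, and without in-vorinostat replicate 2 that of cholesterol synthesis was 0.17. With normexp the class II median was 1.52 and the cholesterol median 0.19. Proteasome genes had 1 higher and 5 lower of 32 [1 and 2], median −0.11 (adjusted p = 0.450). Immunoproteasome and MHC class I genes had 7 higher and 3 lower of 17 [8 and 3], median 0.37 (adjusted p = 0.0857, and 0.0387 to 0.0413 in 2 settings that passed).

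The last comparison asked where the drug difference in U937-B8 departed from that in U937, with the lengths of exposure unequal. LMO1 had the largest positive interaction (6.16 ± 0.70, adjusted p = 0.00924), then MYC (5.19 ± 0.32, adjusted p = 0.00515), HLA-DRA (4.12), the chromatin organiser SATB1 (4.02) and PLD6 (3.59). Among the most negative of such genes were ITLN1 (−3.63), the acyltransferase GPAT3 (−3.47), the decoy receptor TNFRSF10C (−3.25) and the formyl peptide receptor FPR1 (−3.18). SQSTM1 (−2.12) and ITGAM (−2.02) also had negative interactions, whereas TXNIP (−1.72, adjusted p = 0.155) did not pass. CDKN1A was above background in neither group without drug, so its interaction was not measured. In limma, 1595 genes (11.4%) passed, 859 positive and 736 negative, and 1284 passed with slide as a block, 1211 of them the same genes; 69.9% of all genes tested had the same sign on both slides. The count was 492 without untreated replicate 1, 416 without untreated replicate 2, 317 without 12 h replicate 2, 443 without washed-off replicate 1, 397 without washed-off replicate 2 and 861 without in-vorinostat replicate 2.

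MYC and ribosome biogenesis genes had positive interactions, 14 positive and 0 negative of 27 [20 and 0], median 0.78 (slides 0.81 and 0.98, adjusted p = 8.09e-11, slide block 1.37e-10, adjusted p = 0.827 with an estimated correlation), including RRS1 (1.71) and WDR43, a processing factor (1.56). Cell-cycle genes had negative ones, 1 positive and 4 negative of 40 [1 and 4], median −0.34 (slides −0.42 and −0.20, adjusted p = 0.0279, slide block 0.0270, adjusted p = 0.827 with an estimated correlation), such as the topoisomerase TOP2A (−1.89) and the thymidine kinase TK1 (−1.21). That list lost its call without untreated replicate 1, washed-off replicate 1, in-vorinostat replicate 1 or the 3 chromosomes (median −0.34), with adjusted p from 0.0565 to 0.104. MHC class II genes had 3 positive and 1 negative of 10 [5 and 1], median 0.99 (adjusted p = 0.0979), and passed in 7 other settings (adjusted p from 0.00312 with normexp to 0.0434 with no filter on dim probes). Thioredoxin and oxidative-stress genes had 0 positive and 4 negative of 24 [1 and 4], median −0.37 (adjusted p = 0.117, and 0.00431 to 0.0244 in 5 settings that passed).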

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

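The tests of explanations in this part were chosen only after the result was seen, while the interaction and the list tests were planned. The drug difference departed between the lines in 1595 genes, the largest being LMO1 (6.16), MYC (5.19), HLA-DRA (4.12), SATB1 (4.02) and PLD6 (3.59) in the positive direction. ITLN1 (−3.63), GPAT3 (−3.47), TNFRSF10C (−3.25) and FPR1 (−3.18) were among the largest of such genes in the negative direction. Cell-cycle genes had a median interaction of −0.34.

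MYC and ribosome biogenesis genes fell after 12 h of vorinostat in U937 and less in U937-B8 kept in the drug, with a median interaction of 0.78. Were scaling between arrays the cause, some other scaling would bring the median near 0, but the smallest over 4 other scalings was 0.68. The median interaction of all genes was −0.02 to 0.07 over these scalings, so the list did not follow an offset shared by all genes. Because the scalings differed so little, the test could not exclude scaling in general. All of them bring arrays to a common level, and a change in the total amount of RNA was not measured. A single slide or array is excluded, since the smallest median over both slides and all left-out arrays was 0.75. The length of exposure to the drug may explain the pattern, because there were 0 arrays of U937-B8 with the 12 h exposure of U937. Resistance and time in the drug could not be told apart for MYC, and arrays of U937-B8 washed off and then given the drug for 12 h would separate them.

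MHC class II genes rose in U937-B8 with drug in the medium (median 2.72), most of all HLA-DRA. Antigen-presenting cells of another type in the cultures would carry HLA-DPA1 and HLA-DPB1 too, and the median of this pair was 0.33, which excludes that source. The B cell genes MS4A1, PAX5 and CD22 were above background on 0 arrays of the group. CD74 and CIITA, whose sequences are unrelated, rose as well, the smaller of their differences being 2.86. Cross-hybridisation between HLA-D probes alone therefore does not account for the class II rise. Whether single HLA-D probes also carried signal from one another was not tested. A single slide or array is excluded by a smallest median of 2.65.

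The untreated and in-vorinostat columns of the value table matched the scanner file of the other replicate of their group at r 0.999 to 1.00, and the cause was not tested.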

How the results depend on the processing

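The setting without genes of 3 chromosomes and the one that kept accessions without a symbol were chosen only after the result was seen. No named gene or list past the threshold changed direction under any setting. Over 802 named gene results, 622 of them past the threshold, no filter on dim probes ended 123 calls, accessions without a symbol 46, slide as a block 31, normexp 25 and quantile normalization 12. Leaving out 1 array ended 42 to 139. All 27 list calls were lost with an estimated correlation, a setting that alters the p-value and not the median; the immunoproteasome and MHC class I list had 0.33 without drug (adjusted p = 0.986) and 0.60 with drug (adjusted p = 0.666).

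Counts moved by over 1.5 times as follows. After 12 h of drug in U937, 2975 genes passed with an added 2-fold threshold. Between the lines without drug, 874 passed with no filter on dim probes, 1058 without the genes of 3 chromosomes, 876 at 2-fold, and 702 to 2190 without 1 array. Between the lines with drug, 2222 passed at 2-fold and 3066 to 5259 without 1 array. For the drug in U937-B8, 2076 passed with no filter, 2316 with only these groups in the fit, 1428 at 2-fold and 1362 to 3300 without 1 array. For U937-B8 in vorinostat against untreated U937, 2004 passed at 2-fold and 2874 to 4472 without 1 array.

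For the interaction, 2814 genes passed with normexp, 234 with no filter, 2721 in the authors' value table, 2845 with trended and robust variance, 2581 with adjustment over 6 contrasts, and 317 to 2129 without 1 array. The drug effect shared by both lines held 1441 genes with no filter and 1039 to 2314 without 1 array. The line difference shared without and with drug held 561 genes with no filter, 680 without the genes of 3 chromosomes, and 498 to 1208 without 1 array.

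Between the lines without drug, list medians in the authors' value table were 0.14 for the proteasome (adjusted p = 0.0493, range over settings 0.0493 to 0.877 apart from the estimated correlation), 0.15 for ER translocation, export and degradation (adjusted p = 0.0471, range 0.0441 to 0.364) and 0.20 for ubiquitin, autophagy and lysosome (adjusted p = 0.0493, range 0.0493 to 0.364). ER translocation, export and degradation had 0.15 with quantile normalization (adjusted p = 0.0441).

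Without the genes of 3 chromosomes 10 list calls were lost, among them MHC class II between the lines with drug (median 0.83 beside 1.27, adjusted p = 0.0544) and thioredoxin in U937 (median 0.59 beside 0.68, adjusted p = 0.0581), and 3 were gained. Most medians stayed about as large, such as −0.54 for granule genes in U937-B8, so these losses do not place the lists on the 3 chromosomes. Quantile normalization and the authors' values ended 2 list calls each.

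The differences between replicates correlated at −0.08 to 0.18 between groups, above 0.1 in 1 of 6 pairs. No strong pairing by replicate number was seen, but weak correlation does not show that the samples were unpaired. Were the replicate labels of the untreated and in-vorinostat scanner files exchanged, replicate number would equal slide. Differences between slides correlated at −0.09 to 0.18 between groups. With a replicate block the counts were 6402, 1858, 5616, 3679, 4895 and 1432 in the order of the report.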

Other observations

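The tests of explanations in this part, the setting without 3 chromosomes and the genes of the next paragraph were chosen only after the result was seen.

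Some further genes were picked from different comparisons, so no statement about a class of genes follows from them. The cathelicidin CAMP rose by 1.37 in U937 after 12 h of drug, while MS4A3 had −3.01. LTF, the lactoferrin of secondary granules, was not above background in untreated U937 and was at least 2.69-fold higher with drug. BPI, a granule protein that binds endotoxin, was at least 8.61-fold higher in washed-off U937-B8 than in untreated U937, where it was not above background. The chemokine CCL7 rose by 2.13 in U937 after 12 h of drug and was not above background in U937-B8, at least 5.05-fold lower than in U937 without drug and at least 15.3-fold lower with drug. The cancer-testis gene SSX4B was above background only in U937-B8, at least 12.2-fold higher without drug and 18.8-fold higher with drug, and CTAG1A was at least 3.80-fold higher in U937 with drug than in untreated U937.

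Genes that share a chromosome differed between U937-B8 and U937 as blocks, with a median of 0.50 on the chromosome of CTSD, −0.36 on that of EMC10 and 0.22 on that of CD74 without drug, and of 0.49, −0.17 and 0.32 with drug. Explanations were tested for the chromosome of CTSD alone. Its smallest excess over other genes was 0.40 under 4 other scalings. An offset common to a whole array cancels in this excess. Only scalings that depend on the signal, such as quantile normalization and normexp, could have removed the excess, and they did not. A single slide or array is excluded by a smallest excess of 0.53. A response of that chromosome to the drug is excluded, because the larger of its drug comparisons had an excess of −0.0542. An offset common to a whole array would move every chromosome, and the other autosomes had medians of −0.15 to 0.02 without drug. Those values argue against such an offset for the chromosomes of EMC10 and CD74. Other effects of scaling, and copy number, stay open for the chromosomes of EMC10 and CD74. The slide medians of these chromosomes without drug (−0.35 and −0.38 for EMC10, 0.28 and 0.17 for CD74) speak against a single slide. For CD74 the drug medians (−0.09 in U937 and −0.03 in U937-B8) speak against a drug response. For EMC10 the drug medians were −0.14 in U937 and 0.04 in U937-B8, with a median interaction of 0.19. A part played by the drug therefore stays open for that chromosome. A different number of copies of the CTSD chromosome in U937-B8 predicted a shift along its whole length, and 20 of 20 stretches of neighbouring genes lay above the other genes, with medians of 0.39 to 0.66 without drug and 0.30 to 0.74 with drug, beside 0.585 for 3 copies against 2. The chromosome was picked for its shift in these data, and 85.1% of its genes lay above 0 without drug and 78.1% with drug. Stretches above the other genes were therefore likely beforehand, and their count is weak evidence for a gained copy. The stretches do show that the shift was not confined to a part of the chromosome. The value of 0.585 presumes 2 copies in U937, which was not measured. No DNA was measured, and counting copies in both lines by sequencing or karyotype would test a gained copy.

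Of 180 measured members of the 6 protein-handling lists, 11 lie on the chromosome of CTSD. It held 6 of the 16 members that were higher without drug, beside 274 of 874 higher genes of any kind, and 8 of the 40 higher with drug, beside 372 of 2672. Because the chromosome was picked for its shift in the same comparisons, these shares say nothing particular about protein handling. Of the 6 that were lower without drug, 2 lay on the chromosome of EMC10. The class I genes are elsewhere, and without the 3 chromosomes the immunoproteasome and MHC class I list had a median of 0.48 and an adjusted p of 3.76e-06 in limma. With all genes and an estimated correlation its adjusted p was 0.986. Whether these genes bear on the response to proteasome inhibitors was not measured on these arrays.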
